A study of Arabidopsis thaliana with 4 samples.

How the data were processed

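RNA was sequenced from developing seeds of Arabidopsis thaliana collected 7 days post anthesis, when embryos were at the torpedo to linear stage, from the wild type and from the erf4 T-DNA insertion line SALK_073394, which the sample titles call erf4_2 and the genotype labels erf4. There were 2 libraries per genotype, read on an Illumina NovaSeq instrument, per the labels. Group and replicate number came from the sample titles. Nothing in the labels says whether the libraries of a genotype came from separate plants or growths. The p-values of single genes therefore measure only the spread between these libraries, which may be technical.

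The authors deposited gene expression as TPM (each gene's share of the transcripts of a library, scaled to 1000000), rounded to 2 decimals, for 33187 identifiers. Every TPM column sums to 1000000 or 1000001. The submitters' processing notes name fastp, HISAT and RSEM without versions, roles or order; the genome build and annotation are not given in the sources used here. The authors also deposited the mean TPM of each genotype, which equals the mean of its 2 library columns and entered no test. TPM keeps no record of how many reads were counted, so the depth of each library is unknown and no interval that needs it is given. An exact 0 may be a failed estimate, and for genes named with such a value the listed values are given, with no fold.

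Of the identifiers, 32548 (98.1%) matched a locus of the RefSeq annotation of TAIR10.1, which served only for gene names, product descriptions, family membership and process terms. Another 354 had names starting with MSTRG, which match no locus of that annotation, and 285 were organelle genes. No coordinates are given because the build behind the file is not named. Tandem or near-identical genes, such as the 2S albumins, the small RuBisCO subunits, the LHCB1 genes and the histones, may share reads, and their single values are uncertain.

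Genes with a TPM of at least 1 in at least 2 of the 4 libraries (20804 genes) were tested on log2(TPM + 1) with limma 3.58.1 in R 4.3.3 (variance trend, two-sided, genotype the only term). Adjusted p-values are Benjamini-Hochberg values from limma, and a gene was called at an adjusted p under 0.05. Fold changes are on the log2(TPM + 1) scale, which understates the change of genes with low values; ratios are of mean TPM. A single comparison of 2 against 2 libraries cannot give a two-sided exact permutation p below 0.333, so no such test was used.

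The test, the filter, 17 gene lists, the alternatives and the rule for naming genes were fixed before the data were examined. Lists with at least 5 measured members were tested against the other genes with limma's camera at a preset correlation of 0.01, together with 2 families (pectin methylesterases and proteins with a pectin methylesterase inhibitor domain), and the 19 p-values were adjusted together. These camera p-values measure a list against the spread across genes, not only between libraries. The same lists were tested with an estimated correlation and with fry, and member p-values were also adjusted over each list alone. Camera with an estimated correlation uses only the residual degrees of freedom of the 4 libraries, which makes it hard for any list to pass. The families were to come from descriptions in the file, which has none, so the TAIR10.1 domain notes were used. Fisher tests of annotation terms among called genes were planned only for 10 or more called genes and terms in the file, and were not run; camera on TAIR10.1 process terms with 10 to 500 tested members was added after the data were seen.

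Genes named are ERF4, the measured members of the homogalacturonan list, up to 4 members with the smallest limma p in each other list, and the 10 higher and 10 lower genes with the smallest p, since no gene was called. For those 20, both libraries labelled erf4 lie outside the wild-type range and the higher genotype mean is at least 5 TPM. Genes named outside this rule are said to have been chosen after their values were seen.

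The tests were checked on simulated values built from the real genes' means and spread. In 10 runs with 20804 genes each, the comparison of erf4 with wild type recovered 0.596% of genes changed 2-fold, 54.0% of those changed 4-fold and 82.9% of those changed 8-fold, and called 46 of 206040 unchanged genes. All 30 lists shifted by 1 on the log2 scale were called, and 1 of 160 unshifted lists. Simulated genes were drawn independently of one another, so these counts do not cover lists whose genes vary together. In the data, estimated correlations ran from -0.12 (cell cycle list) to 0.996 (storage protein list). Alternatives covered the pseudocount (0.1 and 5), the filter (none, and a mean TPM of at least 5), median-of-ratios and quantile rescaling, the variance model, the threshold (an adjusted p of 0.1, or a change of at least 2-fold in addition), the replicate number as a term, the list test, and leaving out each library in turn. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.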

Results

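Transcript levels were measured in whole developing seeds 7 days post anthesis, in 2 wild-type libraries and 2 libraries labelled erf4 (erf4_2 in the sample titles). ERF4 is an ethylene response factor that represses transcription through an EAR motif. Together with the transcription factor MYB52 it is known for its part in the methylesterification of homogalacturonan, a pectin of seed coat mucilage. The comparison asks which seed transcripts differ when ERF4 is mutated. The depth of the libraries is unknown, since the values are TPM. Between 20295 and 20630 genes per library had at least 1 TPM, and the 10 most abundant genes held 8.51% to 11.8% of all TPM in a library.

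The ERF4 transcript was not lower in the libraries labelled erf4. ERF4 (AT3G15210, chromosome 3, 1 exon in TAIR10.1) had 38.0 and 33.0 TPM in the wild type and 34.6 and 41.3 TPM in the libraries labelled erf4. Its log2 fold change was 0.09 (SE 0.17, 95% confidence interval -0.34 to 0.52). An insertion can leave a transcript that still counts towards the gene, and gene-level TPM do not show where reads fall. The values therefore do not check the genotype labels, and every direction given here is from the wild type to the libraries labelled erf4.

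Several genes for the wall and pectin of mucilage-secreting cells had higher values in both libraries labelled erf4 than in either wild-type library, although limma called none of them over all genes. The peroxidase gene PRX36 (AT3G50990), which loosens the outer wall of these cells, had 81.1 and 74.7 TPM in the wild type against 366 and 170 TPM. The pectin methylesterase gene PME58 (AT5G49180) had 186 and 129 TPM against 375 and 279, and the subtilase gene SBT1.7 (AT5G67360), needed for mucilage release, had 428 and 467 TPM against 723 and 698. The inhibitor gene PMEI14 (AT1G56100), among the 20 most abundant transcripts of these seeds, had 2491 and 1312 TPM against 5967 and 2869, while PMEI13 (AT5G62360) went from a mean of 39.0 ± 8.63 to 60.0 ± 12.8 TPM and PMEI15 (AT3G05741) from 2.90 ± 1.69 to 6.08 ± 2.04 TPM (SD, n = 2).

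Of the 18 measured members of the homogalacturonan list, 14 had a positive and 4 a negative log2 fold change, and 7 lay above the wild-type range in both libraries. Over all tested genes, 21.5% lay above that range and 12.2% below it, shares that also apply to such counts for the other lists. PRX36, PME58 and SBT1.7 were called when adjusted over the list alone (limma adjusted p = 0.0481 for the smallest) and no member when adjusted over all genes. Their log2 fold changes were 1.67 (SE 0.37), 1.06 (SE 0.25) and 0.67 (SE 0.16). The list as a whole ranked above the other genes (camera adjusted p = 0.0128, mean log2 fold change 0.38, median 0.09), with an adjusted p = 0.536 with an estimated correlation. PMEI13, PMEI14, PMEI15 and SBT1.7 all lay above the wild-type range in both libraries. They were put on the list because the study of this mutant is known for them, so the count is not independent evidence of the list's direction. Without these genes the list was not past the threshold (mean 0.24, camera adjusted p = 0.258). Without erf4 replicate 1 it was not either, although its mean stayed at 0.37 (adjusted p = 0.0663). Of the 12 remaining members, whose log2 fold changes ran from -0.46 to 0.54, the lowest was BLH4 (AT2G23760) and the highest STK (AT4G09960). MYB52 (AT1G17950) had 6.60 and 3.04 TPM against 4.70 and 4.30, and the pectin methylesterase gene HMS (AT5G19730), the inhibitor gene PMEI6 (AT2G47670) and PME16 (AT2G43050) had log2 fold changes of 3.04e-04, 0.54 and 0.04. The genes for the ubiquitin ligases FLY1 (AT4G28370) and FLY2 (AT2G20650) stood at 0.04 and -0.16, and those for the regulators BLH2 (AT4G36870), LUH (AT2G32700), LUG (AT4G32551) and SEU (AT1G43850) between -0.03 and 0.15.

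**Figure D1:**
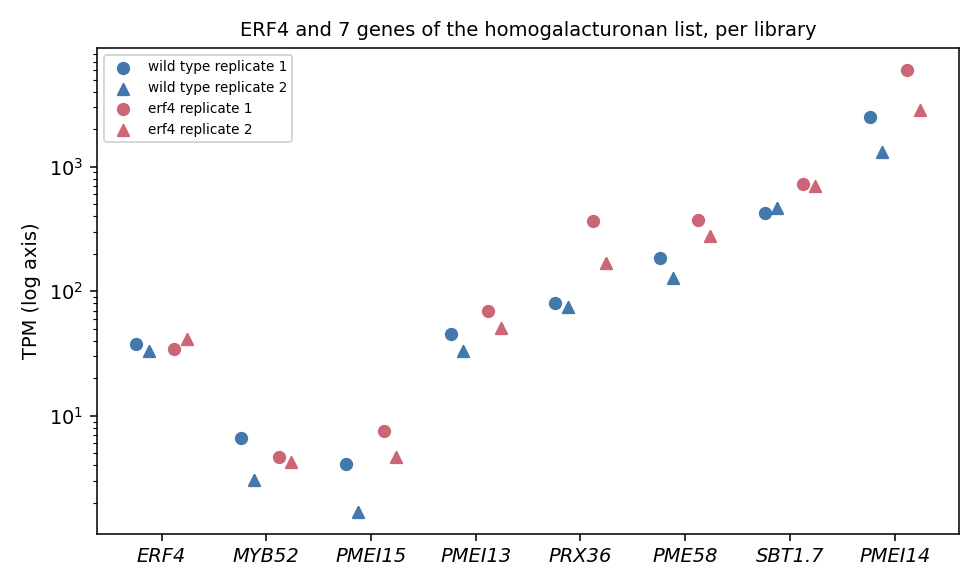
TPM (log axis) of ERF4 and 7 members of the homogalacturonan list in each library; circles are replicate 1, triangles replicate 2, blue the wild type and red the libraries labelled erf4. ERF4 and MYB52 overlap between the genotypes, whereas PRX36, PME58, SBT1.7, PMEI13, PMEI14 and PMEI15 lie higher in both libraries labelled erf4 than in either wild-type library.

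Proteins with a pectin methylesterase inhibitor domain formed the family with the broader difference. Of 40 measured genes, 33 had a positive log2 fold change and 16 lay above the wild-type range in both libraries, against 3 below it. The family ranked above the other genes (camera adjusted p = 9.64e-04, mean log2 fold change 0.36; adjusted p = 0.525 with an estimated correlation), and still did when the 4 members shared with the homogalacturonan list were set aside (adjusted p = 0.00724, mean 0.31). Without wild type replicate 2 its mean was 0.22 (adjusted p = 0.00700). No single member was called, over all genes or over the family alone. Pectin methylesterases themselves went both ways, with 19 of 29 positive, and the family was not past the threshold (camera adjusted p = 0.108). Within it 5 genes were called when adjusted over the family alone, and none over all genes. AT1G11590 had 30.9 and 32.2 TPM against 76.8 and 80.3 (2.49-fold, log2 fold change 1.29, SE 0.14), AT1G11580 (PMEPCRA) had a log2 fold change of 0.83, AT4G03930 of 0.98 and PME58 of 1.06. AT5G20860 went the other way, with 23.4 and 6.42 TPM against 1.75 and 1.47. AT1G11580, AT4G03930 and AT5G20860 were named after their values were seen.

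Genes that build mucilage polysaccharides did not pass as a list. Of 18 measured, 9 were positive and 9 negative, 7 lay above the wild-type range in both libraries and 1 below it (camera adjusted p = 0.891). The list's mean (-0.08) and median (0.01) differ in sign. Its mean was -0.31 without erf4 replicate 2 and 0.16 without erf4 replicate 1. GATL5 (AT1G02720), a glycosyltransferase gene that affects mucilage pectin, had the smallest p, with 113 and 202 TPM in the wild type against 42.6 and 70.4 (log2 fold change -1.45, SE 0.36, limma adjusted p = 0.521). The rhamnosyltransferase gene RRT1 (AT5G15740) stood at -0.68, and the genes for the wall enzyme BXL1 (AT5G49360) and the COBRA-like protein COBL2 (AT3G29810) at 0.56 and 0.30, none of them called. Among seed coat transcription factors, MYB5 (AT3G13540), TT2 (AT5G35550), MYB61 (AT1G09540) and KNAT3 (AT5G25220) lay above the wild-type range, with log2 fold changes of 0.40, 0.58, 0.37 and 0.36; the list of 14 was not past the threshold (camera adjusted p = 0.103). Cellulose synthases were not either (adjusted p = 0.229, 7 of 8 positive), with CESA9 (AT2G21770) at -0.65 and the secondary wall genes CESA4 (AT5G44030), CESA7 (AT5G17420) and CESA8 (AT4G18780) at 0.60, 0.61 and 0.51. Without wild type replicate 1 the cellulose synthase list passed (adjusted p = 0.00713, mean 0.41), whereas without wild type replicate 2 its mean was -0.02 (adjusted p = 0.909).

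The fixed list of genes for flavonoids and for the proanthocyanidins of the inner seed coat was higher in the libraries labelled erf4. Of 15 genes, 14 were positive and 8 lay above the wild-type range in both libraries (camera adjusted p = 1.42e-05, mean log2 fold change 0.68; adjusted p = 0.552 with an estimated correlation). BAN (AT1G61720), which encodes anthocyanidin reductase, had 299 and 223 TPM against 476 and 398. DFR (AT5G42800) had 177 and 91.9 TPM against 368 and 226, LDOX (AT4G22880) 242 and 136 against 453 and 330, and TT19 (AT5G17220) 119 and 76.2 against 227 and 154. The process term for flavonoid biosynthesis, added after the data were seen, had 7 of 15 genes positive (median log2 fold change -0.003, camera adjusted p = 0.796). No gene of the fixed list was called singly. The level of this list depended on the libraries: the mean was 0.49 without erf4 replicate 1 (adjusted p = 0.0735, no longer past the threshold), 0.34 without wild type replicate 2 and 1.03 without wild type replicate 1.

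Cell cycle and DNA replication genes were higher by a small and even amount. All 9 measured genes lay above the wild-type range in both libraries labelled erf4, with a mean log2 fold change of 0.42 (SD 0.15 across genes; camera adjusted p = 9.45e-06; adjusted p = 0.525 with an estimated correlation). Broader process terms leaned the same way but were not past the threshold of camera. DNA replication had 31 of 40 genes positive (adjusted p = 0.138), regulation of cell cycle 26 of 32 (adjusted p = 0.299) and cell cycle 9 of 13 (adjusted p = 0.349). The replication clamp genes PCNA1 (AT1G07370) and PCNA2 (AT2G29570) had 21.2 and 22.5 TPM against 36.4 and 31.8, and 27.0 and 27.0 TPM against 39.3 and 39.2. The cytokinesis syntaxin gene KNOLLE (AT1G08560) had 166 and 155 TPM against 254 and 217. These 3 genes were called when adjusted over the list alone (smallest limma adjusted p = 0.0459) and none over all genes; CDKB1;1 (AT3G54180) stood at 0.55. This was the one list also past the threshold with fry (adjusted p = 0.0222), and leaving out any single library kept it past the threshold.

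Photosynthesis genes were also higher as a list, with 12 of 13 positive (camera adjusted p = 9.64e-04, mean log2 fold change 0.59; adjusted p = 0.594 with an estimated correlation). RuBisCO activase, RCA (AT2G39730), had 664 and 309 TPM against 957 and 775, LHCB2.1 (AT2G05100) 864 and 462 against 1247 and 874, and the genes RBCS1B (AT5G38430) and LHCB3 (AT5G54270) had log2 fold changes of 0.49 and 0.52. The mean of the photosynthesis list was 0.12 without wild type replicate 2 (adjusted p = 0.274), 0.38 without erf4 replicate 1 (adjusted p = 0.557) and 1.05 without wild type replicate 1. Silique wall and leaf markers lay above the wild-type range in 7 of 10 cases, though not past the threshold as a list (adjusted p = 0.103).

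**Figure D2:**
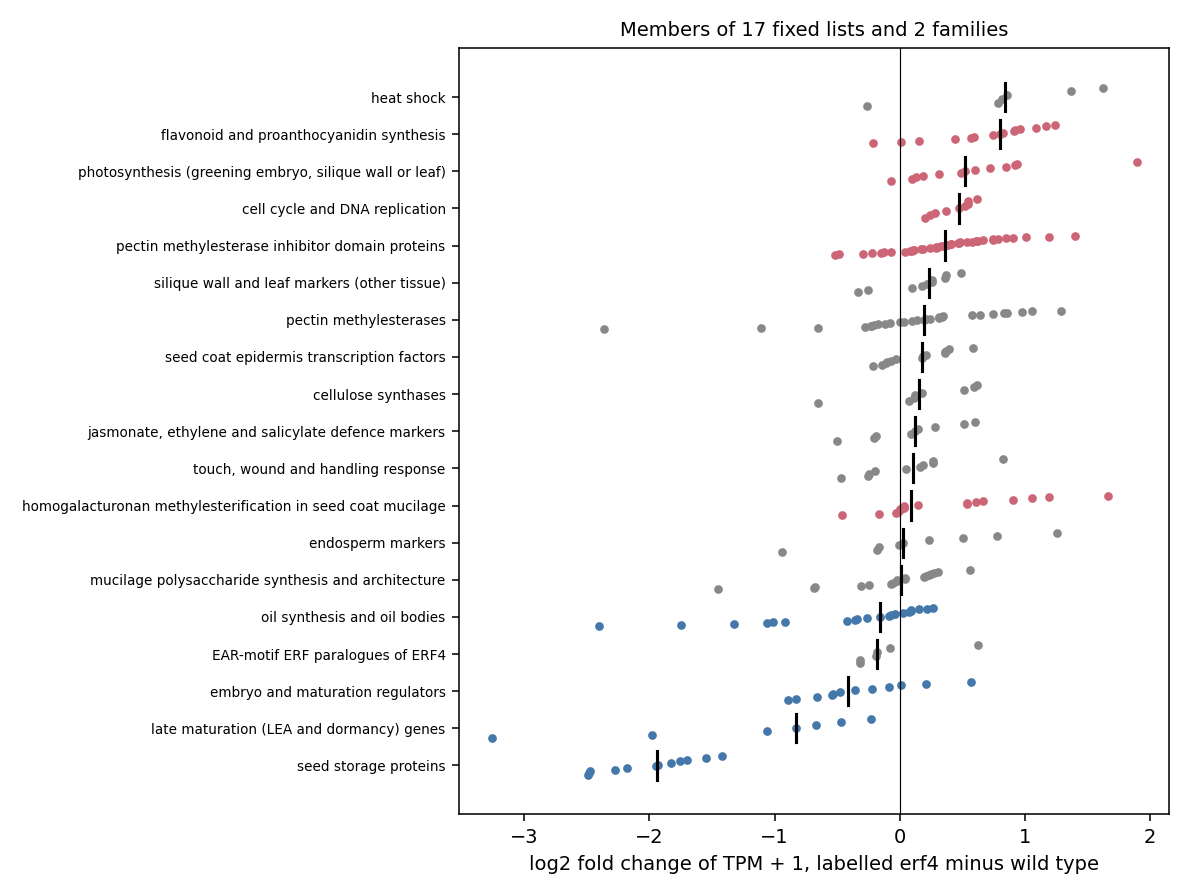
Log2 fold change (labelled erf4 minus wild type, TPM + 1) of each measured gene in the 17 lists and 2 families; bars are list medians, and lists past the threshold of camera at the preset correlation are red (higher) or blue (lower), the others grey. Cell cycle genes lie close together around a median of 0.47, whereas storage protein genes lie around -1.94.

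Lists of seed filling and maturation genes ranked below the other genes, but the storage protein list was low in erf4 replicate 2 and not in erf4 replicate 1. Relative to each gene's mean, its median log2 level was 1.56 and 0.56 in the wild type, 1.76 in erf4 replicate 1 and -3.50 in erf4 replicate 2. All 12 storage protein genes had a negative log2 fold change (camera adjusted p = 7.93e-05, mean -2.00; adjusted p = 0.552 with an estimated correlation), and 2 lay below the wild-type range in both libraries. The 12S globulin gene CRA1 (AT5G44120) had 3283 and 2750 TPM in the wild type against 2311 and 309, and the vicilin-like AT2G18540 had 48.4 and 35.1 against 17.7 and 5.37. The vicilin-like AT2G28490 and PAP85 (AT3G22640) had log2 fold changes of -1.75 (SE 1.02) and -2.18 (SE 1.38). The 2S albumin gene SESA3 (AT4G27160), named after its values were seen, had 9387 and 4932 TPM against 10649 and 137. Without erf4 replicate 2 the storage list was higher, not lower (mean 0.56, adjusted p = 0.0826), and without erf4 replicate 1 its mean was -4.56, so its direction rests on erf4 replicate 2.

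Of the oil genes, 14 of 21 were negative (camera adjusted p = 9.64e-04, mean -0.44; adjusted p = 0.525 with an estimated correlation). The fatty acid elongase gene FAE1 (AT4G34520) had 104 and 119 TPM against 52.2 and 56.9 (log2 fold change -1.01, SE 0.15), and was called when adjusted over the list alone (limma adjusted p = 0.0177) but not over all genes. The oleosin genes OLEO3 (AT5G51210) and OLEO2 (AT5G40420) had 1197 and 1410 TPM against 734 and 644, and 1040 and 1086 against 744 and 241, and BCCP2 (AT5G15530), for a subunit of acetyl-CoA carboxylase, stood at -0.34. Without erf4 replicate 2 the list had a mean of -0.23 and was not past the threshold (adjusted p = 0.141). All 7 measured late maturation genes were negative (camera adjusted p = 7.69e-05, mean -1.21; adjusted p = 0.536 with an estimated correlation). HSD1 (AT5G50600), an oil body steroleosin gene, had 282 and 81.6 TPM against 15.6 and 14.3, and the LEA gene ECP63 (AT2G36640) 24.9 and 18.1 against 12.1 and 10.9; both were called when adjusted over the list alone and neither over all genes. The peroxiredoxin gene PER1 (AT1G48130) and RAB18 (AT5G66400) stood at -1.98 and -0.67. The mean of this list was -0.77 both without erf4 replicate 2 (adjusted p = 0.0826, no longer past the threshold) and without wild type replicate 1.

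Regulators of embryo development and maturation were lower in 9 of 12 cases (camera adjusted p = 0.00129, mean -0.32; adjusted p = 0.552 with an estimated correlation). The bZIP factor gene BZIP67 (AT3G44460) had 48.5 and 61.1 TPM against 28.1 and 32.6, FUS3 (AT3G26790) 145 and 175 against 63.4 and 115, and L1L (AT5G47670) 197 and 214 against 112 and 151. LEC1 (AT1G21970), which acts early in the embryo, went the other way with 74.0 and 78.2 TPM against 118 and 110. BZIP67 and LEC1 were called when adjusted over the list alone (limma adjusted p = 0.0444 for the smallest) and neither over all genes. The mean was -0.09 without erf4 replicate 1 and -0.55 without erf4 replicate 2. Endosperm markers did not pass as a list, with 5 of 9 positive, 4 above the wild-type range and 1 below it (camera adjusted p = 0.359). Among them the imprinted gene PHE1 (AT1G65330) had 2.51 and 2.18 TPM against 8.07 and 6.06, and EPR1 (AT2G27380) 1530 and 1189 against 779 and 633; both were called when adjusted over the list alone. FWA (AT4G25530) and FIS2 (AT2G35670) stood at 0.78 and 0.51.

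**Figure D3:**
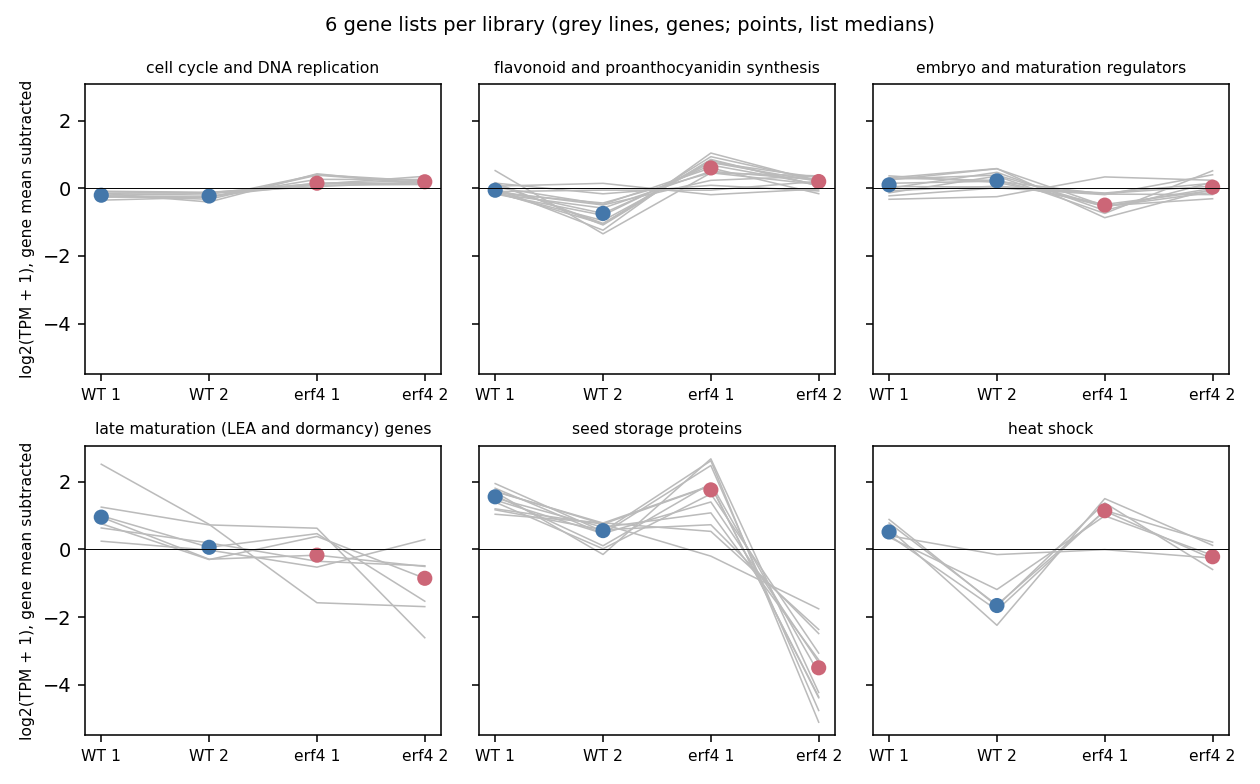
Log2(TPM + 1) minus each gene's mean over the 4 libraries, for 6 lists; grey lines join the values of 1 gene, and points are list medians (blue, wild type; red, labelled erf4). Cell cycle medians are -0.20 and -0.23 in the wild type and 0.15 and 0.19 in the libraries labelled erf4, whereas the storage protein median is -3.50 in erf4 replicate 2 and positive in the other 3 libraries.

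Markers of other tissue and of handling did not pass. The silique wall and leaf list had 8 of 10 positive, 7 above the wild-type range in both libraries and 2 below it (camera adjusted p = 0.103), with TGG2 (AT5G25980), SHP1 (AT3G58780), FIL (AT2G45190) and TGG1 (AT5G26000) at 0.49, 0.37, -0.25 and 0.26. Touch and wound genes had a mean of 0.06, which ran from -0.36 without erf4 replicate 2 to 0.48 without erf4 replicate 1, although camera placed the list lower (adjusted p = 0.833); ZAT10 (AT1G27730), WRKY40 (AT1G80840), WRKY53 (AT4G23810) and ERF2 (AT5G47220) stood at -0.47, 0.82, 0.26 and 0.27. Defence markers (adjusted p = 0.796) included PR2 (AT3G57260) at 0.60, PR5 (AT1G75040) at 0.52, JAZ1 (AT1G19180) at -0.19 and PR4 (AT3G04720) at -0.50, and passed without erf4 replicate 2 (adjusted p = 0.0403). The ERF4 paralogues with an EAR motif were negative in 5 of 6 cases (adjusted p = 0.123), with ERF8 (AT1G53170), ERF12 (AT1G28360), ERF11 (AT1G28370) and ERF7 (AT3G20310) at -0.31, -0.32, 0.63 and -0.18. Heat shock genes differed more between replicates than between genotypes (camera adjusted p = 0.154): HSP90.1 (AT5G52640) had 133 and 28.0 TPM against 222 and 116, HSFA2 (AT2G26150) 40.5 and 4.74 against 75.8 and 28.5, HSP17.6A (AT5G12030) 47.8 and 8.11 against 61.4 and 22.4, and HSP101 (AT1G74310) had a log2 fold change of 0.82. That list passed without wild type replicate 1 (adjusted p = 2.26e-08, mean 1.88) and without erf4 replicate 2 (adjusted p = 0.0263, mean 1.46), while its mean was -0.15 without wild type replicate 2 (adjusted p = 0.488) and 0.27 without erf4 replicate 1 (adjusted p = 0.557).

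Across all 20804 genes, limma with genotype as the only term called none (smallest adjusted p = 0.171). With the replicate number as a further term it did call genes, as given in the section on processing. With genotype alone, 1452 genes had an unadjusted limma p under 0.05, where 1040 would be expected by chance. Replicate 1 of both genotypes against replicate 2 gave 1758 such genes, and the remaining division of the 4 libraries 232. A count above 1040 was therefore not particular to genotype. Of the 1452 genes, 881 were higher and 571 lower. With median-of-ratios rescaling the split was 693 higher and 797 lower, and with quantile normalization 765 and 778. Without erf4 replicate 2 it was 756 higher and 1239 lower, and without wild type replicate 1 it was 1304 and 515. Both libraries labelled erf4 lay above the wild-type range for 4463 genes (21.5%) and below it for 2539 (12.2%), against 16.7% each by chance. Leaving out a wild-type library gave calls, 204 without replicate 1 and 49 without replicate 2, each with a lone wild-type library assumed to vary like the pair labelled erf4.

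The genes with the smallest p, none of which passed, included the pectin methylesterase gene AT1G11590 and a homeodomain factor gene. HDG3 (AT2G32370), a homeodomain transcription factor gene, had a mean of 23.3 ± 3.37 TPM in the wild type and 67.4 ± 8.34 TPM in the libraries labelled erf4 (SD, n = 2; 2.89-fold; limma adjusted p = 0.279). The carotenoid dioxygenase gene NCED4 (AT4G19170) had 40.5 ± 1.13 and 81.5 ± 6.29 TPM, and AT3G42830, which encodes a RING/U-box protein, 7.65 ± 0.198 and 26.9 ± 6.87 TPM. AT5G26805, with a B3 domain, had a log2 fold change of 1.88, and the thionin gene AT2G20619 was listed at 1.26 and 0 TPM against 9.04 and 9.83. On the lower side, AT1G62225, of unknown function, had 2093 and 2547 TPM against 516 and 384 (log2 fold change -2.37, SE 0.24, limma adjusted p = 0.223), and AT2G23400, an undecaprenyl pyrophosphate synthetase family gene, 15.3 and 14.9 TPM against 1.42 and 2.03 (limma adjusted p = 0.171). The noncoding locus AT1G05333 and the unannotated loci MSTRG.21147 and MSTRG.15041 were also among the 10 lower genes. The other 9 of the 20 were listed at 0 in both libraries of a genotype. In the libraries labelled erf4, AT1G08317 was listed at 12.4 and 10.3 TPM, MIR5021 at 7.58 and 12.6, AT3G08235 at 20.6 and 8.54 and the mitochondrial ATMG01380 at 46.5 and 274, all at 0 in the wild type. In the wild type, AT4G07365 was listed at 10.8 and 18.3 TPM, AT2G07345 at 10.9 and 7.11, AT2G09435 at 9.01 and 6.10 and the small nuclear RNA genes U1.8 (AT5G04455) and U12 (AT1G61275) at 19.3 and 11.4 and at 14.0 and 8.5, all at 0 in the libraries labelled erf4.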

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

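Setting aside pectin list members was chosen only after the results were seen; the other alternatives were planned. No gene was called by limma with either pseudocount, either filter, either rescaling, either variance model or either other threshold, and 1025 to 1652 genes had an unadjusted p under 0.05 under these settings, against 1452. Leaving out 1 library gave 0 to 204 called genes, 906 to 1995 genes at an unadjusted p under 0.05, 5 to 10 lists past the threshold, and ERF4 log2 fold changes from -0.03 to 0.22, with a lone library assumed to vary like the other pair. Without erf4 replicate 2, the storage list reversed to a mean of 0.56 (range over left-out libraries -4.56 to 0.56), which follows from that library's low values. With the estimated correlation 0 lists and 0 families passed, and with fry 1 list and 0 families, against 8 lists and 1 family. The correlation alone does not account for this. Estimates for the cell cycle (-0.12) and oil (0.009) lists were below the preset 0.01. Their unadjusted camera p still rose, from 4.97e-07 to 0.0347 and from 3.34e-04 to 0.0686. Other called lists had estimates above the preset. With an estimated correlation, camera also uses the residual degrees of freedom of the 4 libraries in place of those of all genes. That raises p-values even where the estimate is low, so a list that does not pass is not thereby shown to have correlated genes. Under the pseudocounts, filters and rescalings the count of lists stayed at 8. The alternative variance models applied to the tests of single genes only and did not enter the list test.

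The replicate numbers are shared by the genotypes, but the labels do not say that a number marks a shared batch. Deviations from the genotype means correlated at 0.351 across genes between libraries of the same number, from only 2 pairs. With the replicate number as a block, limma called 1083 genes (627 higher, 456 lower), and 2901 had an unadjusted limma p under 0.05. With the block 9 lists passed, heat shock being the addition (camera adjusted p = 4.87e-06). The blocked fit has fewer residual degrees of freedom per gene than the main one, so its calls rest more on the spread shared across genes.

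Of 102 named genes other than ERF4, 59 were called with the block, against 1083 of all 20804 genes. None was called in the opposite direction under any alternative, and 29 of 1291 values had the other sign, none of them called. Most of these genes were named for a small limma p in these same libraries, so neither count is independent support for them. Because TPM hold no read counts, the precision of low values cannot be given.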

Other observations

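The genes in the next paragraph, the process terms, the split by replicate number, and the tests on sample labels, embryo share and abundant transcripts were chosen only after results were seen; the tests on clock genes and on histone and LEA genes were written before those values were looked at, although LEA4-5 and the nucleosome assembly term had been seen.

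Among the 20 transcripts with the highest mean, 6 lay below the wild-type range in both libraries labelled erf4 and 6 above it, against 12.2% and 21.5% of all tested genes; limma called none, and the 20 were not tested as a group. AT5G38160, a lipid transfer protein-like gene and the most abundant transcript in every library, had 29491 and 35676 TPM in the wild type against 17362 and 21725. Of the genes of unknown function with neighbouring locus numbers, AT1G62060 had 15011 and 22545 TPM against 7222 and 11728, and AT1G62070 had 3336 and 6381 against 1025 and 1455. The germin-like gene GER2 (AT5G39190) had 6424 and 7734 TPM against 3772 and 2693. In the other direction, the thiol reductase gene AT4G12960 (GILT) had 6006 and 4558 TPM against 16677 and 8382, and LTP3 (AT5G59320) had 2677 and 2080 against 6072 and 3386. Copies within these families may share reads, so their single values are uncertain.

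Of 250 process terms, 5 passed with camera at the preset correlation and 0 with an estimated correlation (adjusted p = 0.996). Lipid storage was lower (mean log2 fold change -0.97, adjusted p = 9.71e-08). Response to heat (0.38, adjusted p = 0.00149), microtubule-based movement (0.22, adjusted p = 0.0172), nucleosome assembly (0.15, adjusted p = 0.0278) and protein catabolic process (0.19, adjusted p = 0.0292) were higher.

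ERF4 was not lower in the libraries labelled erf4, with a log2 fold change of 0.0915 whose upper 95% limit is 0.52. An exchange of labels that hid a loss of ERF4 would leave a library with little ERF4, and the lowest value of the 4 libraries was 33.0 TPM against a highest of 41.3, so an exchange does not account for these values, although in a line that keeps the transcript they would not reveal one. Libraries labelled erf4 that were made from wild-type seeds and an insertion that leaves the transcript in place cannot be told apart from gene-level TPM, because both allow an unchanged ERF4 value. PMEI13, PMEI14, PMEI15 and SBT1.7 all lay above the wild-type range in both libraries, as did all members of 0.29% of 10000 random sets of 4 genes matched on expression. A rule written first would have taken that share as excluding wild-type seeds in these libraries, and was dropped once the 4 genes had been seen to be higher, because they were taken from the study of this mutant and may have been picked there for being higher in these libraries.

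Replicate number separated the libraries at least as well as genotype: replicate 1 of both genotypes against replicate 2 gave 4 calls and 1758 genes at an unadjusted p under 0.05, against 0 and 1452 for genotype and 0 and 232 for the remaining split of the 4 libraries. Different hours of collection are a candidate explanation for part of this: morning clock genes were lower relative to evening ones in replicate 2 by a median log2 difference of -1.74 in the wild type and -1.54 in the libraries labelled erf4, with CCA1 (AT2G46830) at 22.5 and 20.5 TPM in replicate 1 against 5.50 and 14.1 in replicate 2, and ELF4 (AT2G40080) at 11.8 and 10.3 against 29.6 and 27.7. A smaller share of embryo in erf4 replicate 2, which could lower its storage transcripts (median log2 difference -5.17 from replicate 1), would also lower embryo regulators, but these had a median difference of 0.42 (SD 0.39 across genes), which argues against it. Whether hour of collection bears on the storage transcripts was not tested, and a difference in seed age between the replicates stays open.

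The cell cycle list was higher and the late maturation, oil and embryo regulator lists lower in the libraries labelled erf4, as slightly younger seeds might also show, while the storage protein list was lower in erf4 replicate 2 and not in erf4 replicate 1 (mean 0.56 without replicate 2). None of these lists passed with an estimated correlation (adjusted p from 0.525 to 0.552), and late maturation (0.0826) and oil (0.141) were not past the threshold without erf4 replicate 2. The 40 core histone genes had a median log2 fold change of 0.22 (33 positive), above the bound of 0.2 set for younger seeds, and would have had 0.25 with 3 histone-fold proteins that were left in at first; the 32 LEA genes had a median of -0.19 (19 negative, quartiles -1.19 and 0.18), short of the bound of -0.2, although camera placed the histones higher (adjusted p = 1.39e-06) and the LEA genes lower (mean -0.55, adjusted p = 2.49e-04), and neither passed with an estimated correlation (adjusted p = 0.24 for both). Younger seeds therefore cannot be told apart from an effect of the erf4 genotype on seed development, which stays open and untested. All libraries carry the same stage label, no measure of stage apart from expression was used, and the LEA genes go both ways. Whether seed age also bears on the homogalacturonan, inhibitor domain and flavonoid lists was not tested. For the cell cycle and storage lists, a few abundant transcripts shifting all TPM are argued against by median-of-ratios rescaling. It moved log2 fold changes by a median of only -0.04. The cell cycle list then had a mean of 0.39 and the storage list a median of -1.98. The cell cycle list also stayed past the threshold (camera adjusted p = 9.51e-06). Camera compares a list with the other genes, so a shift of all genes alike could hardly change that result, and it decides nothing here. The argument from the small shift does not extend to the split of genes at an unadjusted limma p under 0.05, which the rescaling turned to 693 higher and 797 lower.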
